A study of Mus musculus with 2 samples.

How the data were processed

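The series holds droplet single-cell RNA sequencing (10x Genomics 5' chemistry) of live CD45+ cells from the colon lamina propria of C57BL/6 mice, as 1 wild type library and 1 library labelled E4BP4 transgenic. How many animals went into a library is not stated in the labels. The deposited tables hold UMI counts for 32285 genes and each barcode of a library. The submitters' processing notes name Cell Ranger 5.0.0, Seurat 4.0 and the mm10 genome, without saying which step each did. The deposited metadata give, per the file headers, the counts of UMIs and genes per cell, the percent of UMIs from mitochondrial genes and from heavy, kappa and lambda immunoglobulin genes, the library name of each cell, and cluster numbers at resolutions 0.4 and 0.5 of an integrated shared-nearest-neighbour graph. Features tables pair gene identifiers with symbols, per the file headers, and 38 symbols occur more than once, for which the first identifier was used. Coordinates were matched by identifier to an annotation of the same build, for 441 of 441 named genes.

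No cell filter is stated in the labels. The metadata cells were those with over 200 and under 2200 genes, under 5% mitochondrial UMIs and under 5% of each immunoglobulin class: of the barcodes that pass these limits 6460 and 7020 were kept and 0 were left out, and 6 in each library were kept outside them. The barcodes not kept were 1218 and 1160 for immunoglobulin, 449 and 664 for mitochondrial share, 1718 and 1290 for gene number and 4 and 3 for few genes. They hold 70.4% and 66.1% of the UMIs, and some of their values appear with the results and in the closing section.

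The 10 coarser deposited clusters carry numbers, and they were named from marker lists fixed before the data were examined, as were the gene lists, the rule for named genes and most alternatives. A cluster is called after a cell type only with at least 3 detected markers of it and with no more markers of another type than of its own among its 10 leading genes. The finer cluster led by Arg1, Saa3 and Nos2 had 0 monocyte markers among these. Its name rests on 7 of 10 monocyte markers at least 2-fold up. A lymphoid cluster and a pair of clusters of low UMI number stayed unnamed. Of 499 listed genes 6 were not among the feature names (Bmal1, Mx1, Mx2, Trgc1, Trgc2 and Trgc4). A list for plasma cell secretion was fixed but is not used here, because no deposited cluster is plasma cell-like.

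UMI counts were summed per library and cluster and divided by the total to give CPM. With 1 library per genotype there is no test across animals, so no p-value is given. Ratios of CPM carry exact conditional binomial 95% intervals, levels exact Poisson intervals and shares exact Clopper-Pearson intervals, which cover counting error only. A fold against 0 counts is a bound against a floor of 3 counts. Genes named by rank had at least 50 UMIs over both libraries and a ratio of at least 1.5 or its inverse, and were ranked by the interval bound nearest to 1: 12 each way in macrophage-like cells and 5 each way in other classes with at least 100 cells per library. Immunoglobulin and T cell receptor segments, haemoglobin, mitochondrial and ribosomal genes, predicted models, and genes below 0.1 of their CPM in another cluster of the same library (a level free RNA could give) were left out of that ranking. The comparison with other clusters used deposited clusters and immunoglobulin-rich barcodes only, so free RNA from cells outside them would not be flagged. Nfil3, Il10, Arg1, Mrc1, Il1b, Tnf and Il6 in macrophage-like and monocyte-like cells, and Foxp3, Il10, Il17a, Il22 and Ifng in T-like cells, are always given. List members needed 20 UMIs over both libraries, and a list's median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of expression, as a description of these libraries.

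Doublets were scored per library with Scrublet. Its automatic threshold called 0 and 2 barcodes and did not work, so the 8% with the highest scores (788 and 811 barcodes) were removed in an alternative. Of the doublets that Scrublet simulated, 41.9% and 36.0% reached the lowest score called this way, so many doublets would stay. They made up 12.7% and 12.9% of macrophage-like cells and 4.42% and 3.20% of monocyte-like cells. Barcodes outside the metadata were given the class whose profile made their counts most likely (multinomial, pseudocount 0.1), which gave 83.1% of 6736 held-out cells their deposited class. Alternatives were median-of-ratios scaling, totals without the top 20 genes, other count minimums, a 2-fold size, the mean of per-cell CPM, a stricter cell filter, finer clusters weighted equally, classes from marker lists per cell, and other denominators for shares. Chosen after seeing the data were the finer deposited clusters on their own, the addition of the barcodes above the gene-number limit, and a new Leiden clustering (2000 variable genes, 30 principal components, 15 neighbours, resolution 1). It left out 264 genes, 165 of them leading genes of deposited clusters, and gave 23 clusters, with 84.1% of cells in the same class as before. Each new cluster took the class of the coarser deposited cluster that most of its cells came from. The libraries were pooled for it without the integration that the deposited graph had.

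The calculations were tested on simulated counts with 200 changed genes. These counts were Poisson draws around the pooled levels of each class, the model that the intervals assume. They hold no variation between cells or animals, so the shares check the calculation and not the error rate of the real comparisons. In macrophage-like cells (8137 genes) the interval left out 1 for 73.1% of genes changed 1.5-fold, 95.5% changed 2-fold, 100% changed 4-fold and 4.09% of unchanged genes. In monocyte-like cells (7392 genes) the same shares were 73.1%, 86.6%, 100% and 4.80%, and in neutrophil-like cells (3721 genes) 38.8%, 67.2%, 90.9% and 3.46%. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scanpy 1.11.5 (with Scrublet), leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. Some results are not reported here.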

Results

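Colon lamina propria cells were profiled by droplet single-cell RNA sequencing during recovery from colitis. The colitis was set off with dextran sulphate sodium (DSS), a polymer that damages the colon epithelium, given in drinking water at 2.0% for 7 days and followed by 7 days of plain water. The mice were 8 weeks old, and live cells carrying CD45, the surface protein shared by white blood cells, were sorted on day 14. There was 1 library from wild type mice and 1 library labelled as transgenic for E4BP4 in macrophages, so each genotype has no replicates and no difference could be tested. E4BP4 is a basic leucine zipper transcription factor encoded by Nfil3, and the series asks how its overexpression in macrophages relates to the white blood cells of the recovering colon. The wild type library held 69346746 UMIs (counted molecules) in 9855 barcodes, and the library labelled transgenic held 58884332 UMIs in 10143 barcodes. The deposited clusters cover 6466 and 7026 of these barcodes, with 20511285 and 19962473 UMIs and medians of 2700.0 and 2427.5 UMIs per cell. Levels are CPM, counts summed over the cells of a cluster and scaled to a common total of UMIs, a ratio is the CPM of the library labelled transgenic over that of the wild type library, and intervals are exact 95% intervals that cover counting error only. Values given as a pair list the wild type library first.

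The first comparison asks whether Nfil3 marks the library labelled transgenic. It was not higher there in macrophage-like cells, and other classes went both ways. In macrophage-like cells, Nfil3 (ENSMUSG00000056749, mm10 chromosome 13, 52967209 to 52981073, minus strand) stood at 84.4 CPM (72.8 to 97.3) in the wild type library and at 73.8 CPM (65.3 to 83.1) in the library labelled transgenic, a ratio of 0.874 (0.724 to 1.06). In monocyte-like cells the values were 272 and 235 CPM, a ratio of 0.864 (0.778 to 0.959). Nfil3 was lower in dendritic-like cells of the library labelled transgenic, at a ratio of 0.685 (0.493 to 0.957), and T-like cells had a ratio of 0.935 (0.767 to 1.14). Nfil3 was higher in neutrophil-like cells, at a ratio of 1.41 (1.15 to 1.71) that was 0.976 relative to the shift of all genes there, and in a finer cluster led by Arg1, Saa3 and Nos2, at 1.35 (1.02 to 1.76). It was lower in a finer cluster led by Csf2, Il22 and Calca, at 0.626 (0.420 to 0.938). An unnamed cluster of low UMI number had 0.697 (0.487 to 0.995). An Nfil3 UMI was found in 19.9% and 20% of macrophage-like cells (median depths 3151 and 3082 UMIs), against 1.54% and 1.16% of B-like cells (median depths 2445 and 2235), taken as background. With each cell thinned to 1000 UMIs, leaving out 63 and 72 shallower macrophage-like cells, those shares were 7.32% and 6.29%. Because Nfil3 was not higher in macrophage-like cells, it does not bear out the label, and every direction below rests on the submitted labels alone. When cells were instead put in classes by marker lists, the macrophage-like ratio of Nfil3 was 0.604, and in cells clustered again the monocyte-like ratio was 1.15.

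**Figure D1:**
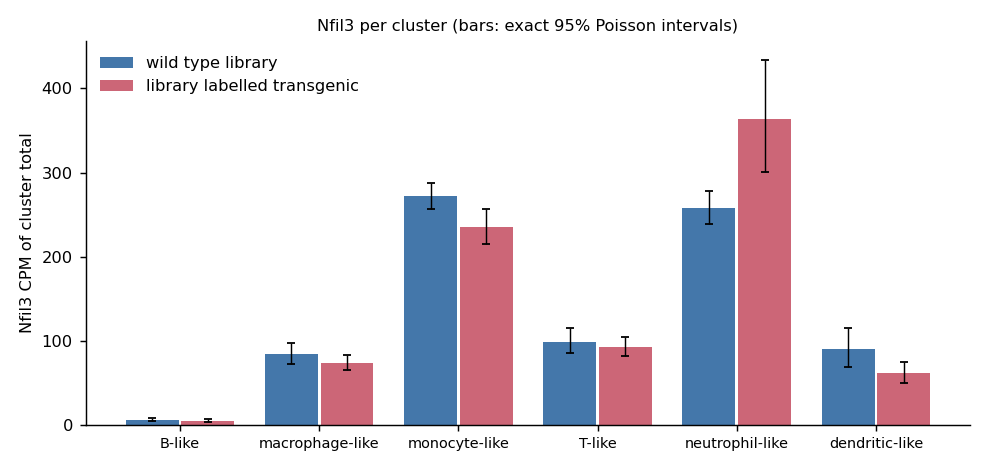
Nfil3 level in CPM of the cluster total (vertical axis) in 6 clusters of the wild type library and the library labelled transgenic, with exact 95% Poisson intervals as error bars. The macrophage-like bars stand at 84.4 and 73.8 CPM with overlapping intervals.

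The next comparison asks how the makeup of the sorted cells differed between the libraries. Neutrophil-like and monocyte-like cells made up less of the library labelled transgenic, and macrophage-like, T-like and dendritic-like cells made up more of it. Neutrophil-like cells were 10.0% (9.30 to 10.8) of 6466 wild type cells and 2.38% (2.03 to 2.76) of 7026 cells of the library labelled transgenic, a ratio of 0.237 (0.199 to 0.282). Monocyte-like cells were 12.6% (11.8 to 13.4) and 6.22% (5.67 to 6.81), a ratio of 0.494 (0.439 to 0.556). Macrophage-like cells were 10.3% (9.54 to 11) and 15.7% (14.9 to 16.6), a ratio of 1.53 (1.39 to 1.69). T-like cells were 7.04% and 10.5%, dendritic-like cells 2.04% and 4.01%, B-like cells 37.3% and 31.8%, and fibroblast-like cells 1.59% and 1.52%. A lymphoid cluster left unnamed, led by Lef1, Tcf7, Csf2 and Il7r, held 7.56% and 15.2%.

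Genes that define the deposited clusters also differed between the libraries, so the cells were clustered again without them. The shares then were 9.98% and 2.25% for neutrophil-like, 13.9% and 4.34% for monocyte-like, 6.42% and 14% for macrophage-like, and 2.52% and 6.06% for dendritic-like cells, the same directions as in the deposited clusters. A new neutrophil-like cluster held 185 wild type cells and 0 cells of the library labelled transgenic. The new clustering did not integrate the libraries, so a technical difference between them could also give such a cluster. New clusters took the class that most of their cells had before, so these shares are not independent of the deposited classes. Within the monocyte-like class, the finer deposited cluster led by Arg1, Saa3 and Nos2 held 24.8% of wild type cells and 11.4% of cells of the library labelled transgenic. An unnamed finer cluster led by Mcpt1, Cd209a, Mcpt2, Cst3 and Fscn1 held 18 and 46 cells of this class (2.21% and 10.5%). The CD45 sort and the filter on cells set the denominators, and barcodes with many immunoglobulin transcripts are not among the deposited cells, so shares of plasma cells cannot be read here.

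**Figure D2:**
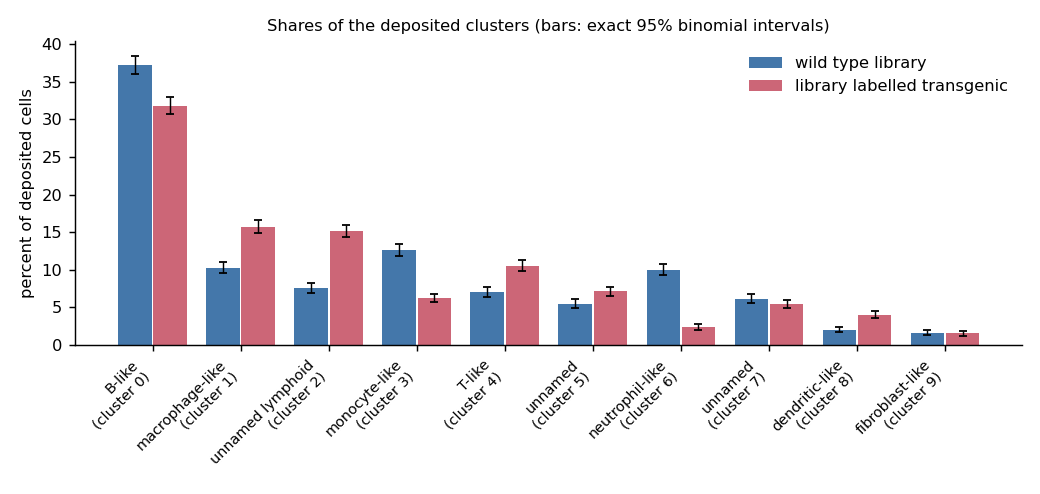
Share of the deposited cells (percent, vertical axis) in each of the 10 coarser deposited clusters for the wild type library and the library labelled transgenic, with exact 95% binomial intervals as error bars. Neutrophil-like cells stand at 10.0% and 2.38%, and macrophage-like cells at 10.3% and 15.7%.

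The main comparison asks how macrophage-like cells (664 and 1106 cells, 2251776 and 3687019 UMIs) differed. By the labels, 16 of 21 monocyte-derived inflammatory genes, 9 of 20 tissue repair and growth factor genes and 8 of 18 glycolysis genes were lower in the library labelled transgenic. Cxcl9, Cd36 and 6 of 24 interferon response genes were higher, while 23 of 24 genes of resident macrophages stayed within 1.5-fold. Fn1 (fibronectin) stood at 205 and 34.4 CPM, a ratio of 0.168 (0.137 to 0.205), Thbs1 (thrombospondin 1) at 639 and 164 CPM, a ratio of 0.257 (0.233 to 0.283), and Spp1 (osteopontin) at 127 and 24.7 CPM, a ratio of 0.195 (0.152 to 0.248). Vegfa, the angiogenic growth factor, had a ratio of 0.295 (0.210 to 0.410), the elastase Mmp12 0.211 (0.147 to 0.299), and the chemokine Ccl24 0.290 (0.226 to 0.369). Cxcl9, a chemokine induced by interferon gamma, stood at 10.2 and 86.8 CPM, a ratio of 8.50 (5.56 to 13.6). It was found in 8 and 51 cells, with 87.0% and 50% of its UMIs in 5 of them. The scavenger receptor Cd36 stood at 26.2 and 101 CPM, a ratio of 3.87 (2.94 to 5.19). On mm10, Cxcl9 (ENSMUSG00000029417) lies on chromosome 5 from 92321347 to 92328079 and Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050. Clustering the cells again moved Spp1 to 0.408, Fn1 to 0.274 and Thbs1 to 0.410.

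Among the genes fixed for naming in macrophage-like cells, Il10, an anti-inflammatory cytokine, stood at 44.9 and 60.5 CPM, a ratio of 1.35 (1.06 to 1.72) that was 1.05 after clustering again. In left-out macrophage-like barcodes above the gene-number limit (339 and 343) it had 84 and 161 UMIs, a ratio of 2.19 (1.67 to 2.88). Il1b, an inflammatory cytokine, stood at 3685 and 2548 CPM, a ratio of 0.691 (0.671 to 0.712), and Tnf at 109 and 75.4 CPM, a ratio of 0.690 (0.579 to 0.823). The mannose receptor Mrc1, one of the genes that lead the deposited cluster, had a ratio of 0.674 (0.621 to 0.731) in the cells clustered without it. Arg1, which breaks down arginine, had 182 and 13 UMIs, a ratio of 0.0436 (0.0228 to 0.0765), at a level that free RNA from other cells could reach, and Il6 had 9 and 5 UMIs, too few to tell (ratio 0.339, 0.0893 to 1.13).

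Other genes named by rank in macrophage-like cells were Retnla, a resistin-like protein, at 63.1 and 405 CPM, a ratio of 6.42 (5.40 to 7.68), with 46.2% of its UMIs in the library labelled transgenic in 5 cells, and Bex3 at a ratio of 3.31 (2.66 to 4.16) and Gbp2b, a guanylate-binding protein, at 4.14 (2.35 to 7.87). Mptx1, a mucosal pentraxin, had 0 and 65 UMIs, at least 13.2-fold higher against a floor of 3 counts. The same gene was among the leading differences of B-like cells and of the unnamed lymphoid cluster (0 and 53 UMIs). Free RNA from cells outside the deposited clusters was not excluded as its source. The lymphocyte genes Klrk1 (8.70), Itgae (6.11), Cd5 (5.77), Cd226 (4.75), Sh2d2a (4.04) and Cd6 (4.01) were also higher, and markers of T cells summed to 189 and 447 CPM in this cluster, a ratio of 2.37 (2.13 to 2.64). Lower by rank were also the mast cell proteases Cma1 (0.0228) and Mcpt4 (0.0587), whose wild type UMIs lay in 5 cells, and Nrg1 (0.0948), Igfbp6 (0.172), Tnfrsf9 (0.261) and Slc7a11 (0.268), a cystine transporter. The mast cell proteases turned direction in other groupings of the cells.

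**Figure D3:**
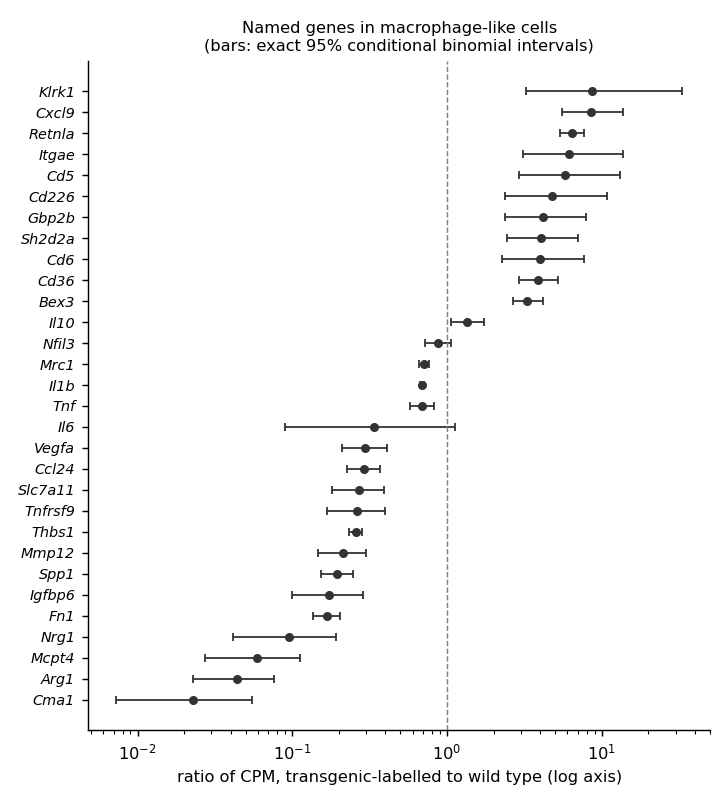
Ratio of CPM in macrophage-like cells, library labelled transgenic over wild type library, on a log axis for each gene named by rank or fixed for naming, with exact 95% conditional binomial intervals. Fn1 stands at 0.168 and Cxcl9 at 8.50, and Mptx1 is left out because its wild type count was 0.

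Of the lists fixed beforehand, monocyte-derived inflammatory genes were lower in macrophage-like cells: 16 of 21 members were at least 1.5-fold lower, 0 were higher, and the median log2 ratio was -0.95, under each of 10000 random lists of the same size and expression (percentile 0). Ccr2, the receptor that draws monocytes from blood, had a ratio of 0.602, Ifitm3 0.457 and Slpi, a protease inhibitor, 0.207. For 13 of these members free RNA could give the level, and among the other 8 members 6 were lower (median -0.84). Neutrophil markers summed to 553 and 118 CPM in the same cluster, a ratio of 0.213 (0.190 to 0.238). Glycolysis genes were lower for 8 of 18 members (median -0.56, percentile 0), with the lactate transporter Slc16a3 at 0.353, Pkm at 0.604 and the hypoxia factor Hif1a at 0.592, and for 4 of 18 (median -0.45) in the finer macrophage-like cluster. Tissue repair and growth factor genes were lower for 9 and higher for 3 of 20 members (median -0.48, percentile 0), with Pdgfb, a platelet-derived growth factor chain, at 2.50 and the collagenase Mmp13 at 1.95 among those higher. In the finer macrophage-like cluster 8 were lower and 3 higher of 20 (median -0.36). Without members that free RNA could give, 5 were lower and 3 higher of 14 there (median -0.15). In the whole class, 7 were lower and 3 higher of 16 without such members (median -0.28). Pro-inflammatory cytokines and mediators were lower for 4 and higher for 1 of 12 members (median -0.47, percentile 0.05), with Ptgs2, the inducible prostaglandin synthase, at 0.454 (0.405 to 0.507), and without 4 members that free RNA could give, 1 was lower and 1 higher of 8 (median -0.40).

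Interferon response genes were higher for 6 of 24 members in macrophage-like cells (median 0.20, percentile 99.9), with Iigp1 at 3.89 and Gbp2 at 1.61, but Irf7 at 0.562. Resident macrophage genes had 23 of 24 members within 1.5-fold (median 0.02, percentile 94.2), with the fractalkine receptor Cx3cr1 at 1.40 and Fcgr1 at 0.702, and this list holds several genes that lead the cluster. Anti-inflammatory macrophage genes had 19 of 23 members within 1.5-fold (median 0.03, percentile 95), with Cd274 at 1.53 and Bcl3 at 0.647. Antigen presentation by class II had 13 of 14 members within 1.5-fold (median 0.08, percentile 95.5), with H2-Ab1 at 1.26 and Cd80 at 0.430. Chemokines went both ways, 3 higher and 7 lower of 18 (median -0.03, percentile 76.4), with Ccl6 at 0.481 and Ccl2 at 0.619. Phagocytosis and lysosome genes had 2 higher and 4 lower of 19 (median -0.06, percentile 55.4), with Gpnmb at 2.03 and Itgam at 0.469. Clock and D-box genes, which include Nfil3 and targets of its binding site, had 1 higher and 2 lower of 14 (median -0.15, percentile 14.9), with Per3 at 0.397. Genes induced by tissue dissociation had a median of 0.31 (percentile 100, 3 higher and 1 lower of 23), with Klf2 at 1.80 and Ier3 at 0.475, and mitochondrial-encoded genes had a median of 0.11 (percentile 97.8, 1 higher of 13).

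**Figure D4:**
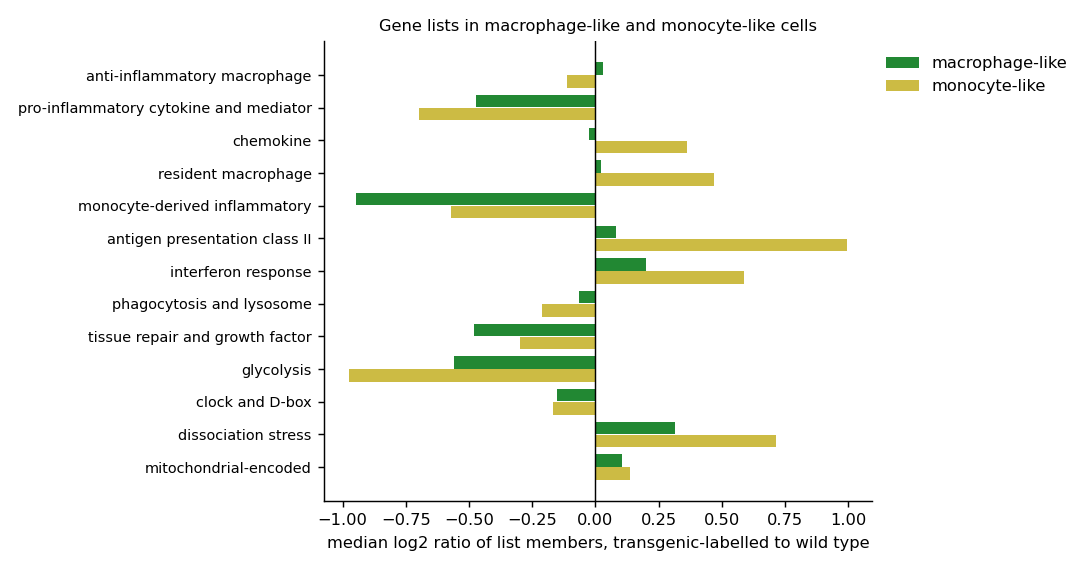
Median log2 ratio over list members, library labelled transgenic over wild type library (horizontal axis), for 13 gene lists in macrophage-like and monocyte-like cells. Monocyte-derived inflammatory genes stand at -0.95 and -0.57, and class II genes at 0.08 and 0.99.

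Monocyte-like cells (814 and 437 cells, 4498873 and 2164921 UMIs) of the library labelled transgenic had, by the labels, higher levels of many class II and interferon response genes and of dendritic cell markers, and lower levels of most glycolysis genes. Cd209a, a lectin of monocyte-derived and dendritic cells, stood at 26.5 and 287 CPM, a ratio of 10.8 (8.90 to 13.3), with Clec4b1 at 9.08 (6.95 to 12.0), Mgl2 at 7.34 (6.08 to 8.90) and the chemokine Ccl12 at 11.7 (6.96 to 21). The unnamed finer cluster with Cd209a among its leading genes held 2.21% and 10.5% of this class, and its part in these ratios was not tested. In the larger finer monocyte-like cluster (636 and 390 cells) Cd209a was at 10.4 (6.88 to 16.3). There it lay in 8 and 33 cells, with 54.4% of its UMIs in the library labelled transgenic in 5 cells. Spp1 stood at 1147 and 30.5 CPM, a ratio of 0.0266 (0.0205 to 0.0339), Lrg1 had a ratio of 0.0514 (0.0313 to 0.08), and Ptges, a prostaglandin E synthase, 0.0504 (0.0259 to 0.0888). Saa3, an acute-phase protein, and Arg1 lead the deposited cluster, and in cells clustered without them they stood at 3243 and 234 CPM (ratio 0.0723, 0.0647 to 0.0805) and at 1263 and 95 CPM (ratio 0.0752, 0.0630 to 0.0890). Retnla stood at 95.6 and 1389.9 CPM, a ratio of 14.5, but 57.7% of its UMIs in the library labelled transgenic lay in 5 cells and the ratio was 0.301 after clustering again. In the larger finer monocyte-like cluster its ratio was 15.3 (13.7 to 17.1), on 14 and 29 cells. In left-out monocyte-like barcodes above the gene-number limit (626 and 73) the ratio was 54.9 (50.6 to 59.6), so its direction depends on how cells were grouped. Clustering again also moved Ccl12 to 3.25, Mgl2 to 3.94 and Clec4b1 to 5.61, and the finer deposited cluster of these cells gave Spp1 a ratio of 0.398.

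Of the genes fixed for naming, Il1b had a ratio of 0.671 (0.658 to 0.684) in monocyte-like cells, Tnf 1.72 (1.43 to 2.08), Il6 2.08 (1.42 to 3.04), Il10 1.13 (0.742 to 1.68) and Mrc1 1.72 (1.43 to 2.07), which was 1.08 after clustering again. In left-out monocyte-like barcodes above the gene-number limit, Il10 had 94 and 26 UMIs, a ratio of 2.21 (1.38 to 3.45). Glycolysis genes were lower for 16 of 19 members (median -0.97, percentile 0), with Bnip3 at 0.182 and Egln3, a hypoxia-induced prolyl hydroxylase, at 0.0884. In the larger finer monocyte-like cluster 7 of 19 glycolysis genes were lower (median -0.54), and 6 of 23 interferon response genes and 7 of 23 dissociation genes were higher. Tissue repair genes there had 7 higher and 4 lower of 20 (median -0.10, percentile 21.6), and anti-inflammatory genes 6 higher and 2 lower of 22 (median 0.12). Pro-inflammatory cytokines and mediators were lower for 8 and higher for 3 of 16 members (median -0.70, percentile 0), with Nos2, the inducible nitric oxide synthase, at 0.118 and Il1a at 0.238. Monocyte-derived inflammatory genes were lower for 10 of 21 members (median -0.57, percentile 0), with the haptoglobin gene Hp at 0.177, S100a8 at 0.0327 and S100a9 at 0.0496, while Ccr2 was at 1.08. Their median was -0.19 after clustering again and likewise -0.19 with barcodes of high gene number added. Markers of neutrophils summed to 2481 and 265 CPM in this cluster, a ratio of 0.107 (0.0981 to 0.116), and markers of type 2 conventional dendritic cells to 398 and 1140.5 CPM, a ratio of 2.86 (2.69 to 3.04). Tissue repair and growth factor genes were lower for 7 and higher for 5 of 20 members (median -0.30, percentile 0.26), with Vegfa at 0.485.

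Class II genes were higher for 9 of 14 members in monocyte-like cells (median 0.99, percentile 100), with H2-Eb1 at 2.66 and H2-Ab1 at 2.44, and interferon response genes for 12 of 23 (median 0.59, percentile 100), with Gbp2 at 2.49. In the larger finer cluster class II genes were higher for 7 of 14 (median 0.63). Without members that free RNA could give, 4 of 11 were higher there (median 0.43). In the finer cluster led by Arg1, Saa3 and Nos2 (217 and 51 cells), 8 of 11 class II and 16 of 16 interferon response genes were higher (medians 1.64 and 2.13). The 51 cells are under the minimum of 100 per library, and few cells could set these values. Of the genes ranked highest there, 5 of the 51 cells held 88.9% of AW112010, 89.5% of Ccl5 and 88.2% of Ly6a UMIs. For Cd83 and Bex3 the shares were 50.5% and 43.8%. The spread of the listed genes over cells is not given here. In that cluster 16 of 19 glycolysis genes were lower (median -1.06). In the whole class, resident macrophage genes were higher for 9 and lower for 1 of 20 (median 0.47, percentile 100), with the efferocytosis receptor Axl at 4.51 and C1qc at 2.27, and this median was 0.05 after clustering again. Chemokines had 4 higher and 4 lower of 18 (median 0.36, percentile 99.98), with Cxcl9 at 2.68 and Cxcl3 at 0.153. Chemokines had 2 higher and 4 lower of 13 without members that free RNA could give (median 0.15), and 10 higher and 2 lower of 17 in the larger finer cluster (median 0.65). Anti-inflammatory genes had 3 higher and 3 lower of 21 (median -0.11, percentile 21.3), with Hmox1 at 0.403 and Il1rn at 0.392. Phagocytosis and lysosome genes had 3 higher and 5 lower of 18 (median -0.21, percentile 4.45), with Ctsl at 0.396, and clock genes 1 higher of 10 (median -0.17, percentile 8.44, and 0.14 after clustering again). Dissociation genes were higher for 15 and lower for 1 of 23 (median 0.72, percentile 100), with Egr1 at 3.98, and mitochondrial-encoded genes were within 1.5-fold for 13 of 13 (median 0.14, percentile 95).

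Neutrophil-like cells (648 and 167 cells, 2533237 and 330432 UMIs) of the library labelled transgenic were lower in the granule genes of immature neutrophils. The median of all genes was 0.53 (log2) higher in the library labelled transgenic, whose cells had a median of 1751 UMIs against 3528.5, so the values in this paragraph are relative to that shift. Camp, a cathelicidin, had 2932 and 0 UMIs, and without taking the shift into account was at least 127-fold lower against a floor of 3 counts. Ngp, which leads the deposited cluster, had a ratio of 0.00274 in cells clustered without it and without taking the shift into account. Counts were 2346 and 4 UMIs for lactoferrin (Ltf, ratio 0.00906), 907 and 1 UMIs for Saa3 (0.00586), and 1551 and 4 UMIs for Prok2 (0.0137). Granule and maturation genes were lower for 14 and higher for 0 of 18 members before that scaling, with a median relative to the shift of -2.91, and this list holds genes that lead the cluster. The medians relative to the shift were -1.39 for neutrophil activation, -1.50 for pro-inflammatory mediators, -0.96 for glycolysis and -0.24 for chemokines. Before the shift is taken into account, chemokines were higher for 6 and lower for 6 of 14 members (median 0.29), and without 5 members that free RNA could give, 2 were higher and 6 lower of 9 (median -1.27). Relative to the shift, medians were 0.41 for interferon response, 0.45 for dissociation, 0.19 for mitochondrial-encoded, 0.01 for anti-inflammatory and -0.03 for clock genes. Il1a was at 0.0551, Il1rn at 0.197, Cxcl1 at 0.0728 and Pgk1 at 0.335, while Ifit3 was at 3.72 and Egr1 at 3.93. The genes of goblet cells Tff3 (24.8), Fcgbp (25.4), Clca1 (26.6) and Zg16 (16.9) and the mast cell protease Prss34 (0 and 52 UMIs, in 1 cell) were higher by rank, and 5 cells held 89.6% of the Tff3 UMIs in the library labelled transgenic. Without taking the shift into account, clustering again lowered the Tff3 ratio from 35.8 to 6.82.

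Dendritic-like cells (132 and 282 cells, 691736 and 1596387 UMIs) of the library labelled transgenic had more transcripts of Cxcl9 and Cxcl10, chemokines induced by interferon, in few cells. These deposited cells are the smaller part of the class, because 300 and 457 barcodes above the gene-number limit were given it as well. With those barcodes added, the class made up 5.28% and 8.89% of cells. Cxcl9 stood at 18.8 and 99.0 CPM, a ratio of 5.27 (2.99 to 10.1), and Cxcl10 had 0 and 68 UMIs, at least 9.82-fold higher against a floor of 3 counts and at a ratio of 4.32 after clustering again. Of these UMIs in the library labelled transgenic, 5 cells held 75.9% for Cxcl9 and 80.9% for Cxcl10, found in 19 and 12 of 282 cells, and Cxcl16 was lower, though within 1.5-fold, at 0.774 (0.646 to 0.928). Il12b, a subunit of interleukins 12 and 23, had 1 and 168 UMIs, a ratio of 72.8 (12.9 to 2892), but 5 cells held 95.2% of the latter and the ratio was 1.56 after clustering again. Bex3 was at 3.43 and Qpct at 4.62, and lower were the interleukin 1 receptor antagonist Il1rn (0.179, 0.131 to 0.242), Tnfrsf9 (0.223), Clec4n (0.271), Bnip3 (0.280) and AA467197 (0.325). Chemokines were higher for 6 and lower for 1 of 12 members (median 0.51, percentile 100), free RNA could give 6 of these members, and the median was 0.04 with barcodes of high gene number added. Medians were 0.10 for class II (percentile 98.9, 2 higher and 1 lower of 14), -0.19 for interferon response (15.6, 2 and 2 of 16), 0.33 for dissociation (100, 6 and 1 of 23), 0.07 for mitochondrial-encoded (96.7, 0 and 0 of 12) and -0.12 for clock genes (46.5, 1 and 0 of 4).

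B-like cells (2410 and 2236 cells, 6315054 and 5419115 UMIs) of the library labelled transgenic had higher levels of some genes of activated and germinal centre B cells and of the interferon response, with most members of both lists within 1.5-fold. Germinal centre and activated B genes were higher for 5 and lower for 1 of 14 members (median 0.31, percentile 100), with Fas at 2.14, Bcl6 at 1.71 and Myc at 0.635. Interferon response genes were higher for 8 of 18 members (median 0.52, percentile 100), with Irf7 at 1.99, and among the 10 members that free RNA could not give, 3 were higher. Bex3 stood at 48.9 and 252 CPM, a ratio of 5.16 (4.55 to 5.85), with Tceal9 at 2.66, Pdzd2 at 3.17, Psme2b at 2.53 and Mptx1 at 1 and 130 UMIs (ratio 151, 26.7 to 6029). Lower were the gut hormone gene Pyy (0.357), the heat shock gene Hspa1b (0.346), Rab29 (0.388), Gpx2 (0.505) and Eps8l1 (0.448). Pyy was lower in an unnamed cluster of low UMI number as well (0.136). For Mptx1 and Pyy, free RNA from cells outside the deposited clusters was not excluded as the source. Immunoglobulin constant genes were higher for 4 of 11 members (median 0.41, percentile 100), and for 0 of the 4 that free RNA could not give. Medians were 0.03 for class II (percentile 83.5, 0 higher and 0 lower of 14), 0.10 for clock (69.0, 2 and 1 of 15), -0.03 for dissociation (37.9, 1 and 4 of 23) and 0.19 for mitochondrial-encoded genes (99.97, 0 and 0 of 13).

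T-like cells (455 and 741 cells, 1757871 and 2668088 UMIs) of the library labelled transgenic had higher levels of some cytotoxic and type 1 genes and a lower level of Il17a. Gzmk, a granzyme, stood at 10.8 and 99.7 CPM, a ratio of 9.22 (5.79 to 15.6), Ifng at 53.5 and 167 CPM, a ratio of 3.12 (2.49 to 3.94), and the chemokine Ccl4 at 396 and 1311 CPM, a ratio of 3.31 (3.05 to 3.6). Cd8b1, a chain of the CD8 coreceptor, was at 3.79 and Ccl3 at 2.51, and lower were Ermn (0.144), Ddit4 (0.361), Phlda1 (0.314), Tnfrsf9 (0.410) and Cystm1 (0.343). Il17a leads the deposited cluster, and in cells clustered without it stood at 130 and 61.4 CPM, a ratio of 0.471 (0.387 to 0.572). Foxp3, the factor of regulatory T cells, had a ratio of 0.677 (0.535 to 0.858), Il10 1.53 (1.18 to 1.99) and Il22 2.65 (2.06 to 3.44). Of the Il22 UMIs in the library labelled transgenic, 5 cells held 99.0%, and clustering again gave Il22 a ratio of 0.366 and Il10 1.06.

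Cytotoxic genes were higher for 6 and lower for 0 of 13 members in T-like cells (median 0.56, percentile 100), and type 1 genes for 6 and 0 of 15 (median 0.42, percentile 100), with the ligand Fasl at 1.84. Both lists hold genes that lead the deposited cluster, among them Ccl5 and Nkg7. Type 3 genes were lower for 4 and higher for 1 of 16 (median -0.22, percentile 0.70), with the homing receptor Ccr6 at 0.449, and naive and central memory genes lower for 3 and higher for 1 of 9 (median -0.36, percentile 0.21), with S1pr1 at 0.425. Regulatory T cell genes went both ways, 3 higher and 5 lower of 23 (median 0.02, percentile 80.7), as did type 2 genes, 3 higher and 3 lower of 10 (median 0.00, percentile 54.5). Glycolysis genes were lower for 7 of 18 (median -0.44, percentile 0), with Pkm at 0.562, and interferon response genes higher for 4 of 16 (median 0.24, percentile 99.6). Medians were 0.08 for clock (percentile 81.9, 2 higher and 1 lower of 13), 0.04 for dissociation (93.6, 1 and 2 of 23) and 0.33 for mitochondrial-encoded genes (100, 0 and 0 of 13). Of the finer deposited clusters called T-like, which together hold more cells than this class, a cluster led by Gzma, Ccl5 and Xcl1 held 291 and 722 cells, a cluster led by Il17a 242 and 359, and a cluster led by Lef1, Dapl1 and Tcf7 167 and 241. Type 1 genes had medians of 0.03 (4 higher and 1 lower of 15), 0.77 (7 and 1 of 13) and 0.25 (2 and 0 of 6) in these clusters. Without members that free RNA could give, the latter pair were 0.41 and 0.11. Cytotoxic genes had medians of 0.15 (2 and 1 of 13), 0.65 (6 and 2 of 12) and 0.74 (4 and 0 of 7), the last being 0.15 without such members. Type 3 genes had medians of 0.47 (1 and 0 of 7), -0.03 (3 and 2 of 16) and 0.42 (2 and 0 of 5, of which free RNA could give 4). Regulatory T cell genes had medians of 0.20 (4 and 2 of 16), 0.16 (7 and 2 of 23) and 0.34 (3 and 2 of 10), while the Foxp3 ratio above is of the whole class. Glycolysis genes had medians of -0.20 (1 and 1 of 18), -0.40 (0 and 6 of 18) and -0.11 (0 and 1 of 14). Interferon response genes had medians of -0.07 (1 and 1 of 15), 0.57 (7 and 0 of 14) and -0.12 (0 and 0 of 9).

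The unnamed lymphoid cluster (489 and 1065 cells) was not scored for gene lists, and genes named by rank are given with their direction in the library labelled transgenic, leaving out Csf2, which leads the cluster. Higher was Xcl1, a chemokine of lymphocytes, at a ratio of 5.39 (4.09 to 7.21), with Cd160 at 6.21 (4.02 to 10.1), Ccl5 at 4.21 (3.95 to 4.48) and Gzmk at 11.5 (3.78 to 57.2), and Mptx1 had 0 and 53 UMIs. Lower were Calca (0.0928, 0.0669 to 0.126), Il17a (0.177, 0.139 to 0.224), Igfbp4 (0.332, 0.286 to 0.385) and the type 2 cytokine Il13 (0.336, 0.235 to 0.479). Several of these rest on few cells: Calca on 27 and 20, Il17a on 35 and 19 and Il13 on 27 and 19. In the library labelled transgenic 5 cells held 59.2%, 77.1% and 64.3% of their UMIs. Gzmk had 3 and 71 UMIs.

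Fibroblast-like cells (103 and 107 cells), which a CD45 sort should leave out, were led by Ccl8 (9.54), Kcna1 (4.15), Ccl21a (3.47), Hspa1b (4.34) and Gsn (2.32) among genes higher in the library labelled transgenic. Rgs5, a gene of pericytes (0.0477), Selp (0.0893) and Madcam1 (0.127), adhesion molecules of vessel walls, Lrg1 (0.165) and Lima1 (0.179) were lower. Most of these rest on few cells: Rgs5 on 10 and 3, Selp on 9 and 2, Madcam1 on 8 and 2, Lrg1 on 13 and 4, Ccl8 on 3 and 10, Ccl21a on 4 and 7 and Kcna1 on 6 and 11. The Rgs5 ratio was 1.42 with barcodes of high gene number added.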

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

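The tests of the S100a9 to S100a8 ratio, of single neutrophil markers and of simulated doublets and both tests on Nfil3 were chosen after the result was seen, and those of doublets, depth and the other neutrophil markers together were written before they were run.

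S100a8 and S100a9, subunits of the neutrophil protein calprotectin, were lower in the library labelled transgenic outside neutrophil-like cells as well: B-like and T-like cells together had 1.14 and 0.0400 UMIs per cell, macrophage-like cells 1.25 and 0.107, and monocyte-like cells 11 and 0.4. Free RNA from neutrophils, whose share was also lower there, is a candidate explanation, and it predicts that neutrophil transcripts keep the ratio they have in neutrophil-like cells. In wild type B-like and T-like cells, the other neutrophil markers per S100a8 and S100a9 UMI were 1.32 times (1.21 to 1.43) their value in neutrophil-like cells, so this source stays open there. That value was 3.17 (2.81 to 3.57) in macrophage-like cells, beyond the limit of 1.5-fold, and 1.57 in monocyte-like cells, with an interval that reaches this limit, but it says little on S100a8 and S100a9 in macrophage-like cells because the excess lay in Csf3r (44.4), Il1r2 (22.2) and Mmp9 (26.3), while Retnlg (0.877) and G0s2 (0.827) kept the neutrophil-like ratio. S100a9 per S100a8 was 0.917 (0.797 to 1.06) of the neutrophil-like value in macrophage-like cells, where free RNA stays open, and 0.593 (0.569 to 0.618) in monocyte-like cells, which argues against free RNA as the whole source there, and a difference in expression by monocyte-like cells between genotypes stays open and untested, since labels and libraries coincide.

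Nfil3 was not higher in macrophage-like cells of the library labelled transgenic. The test of exchanged labels assumed that the transgene transcript is counted under Nfil3 and raises it at least 1.5-fold, a ratio below 1/1.5. The lower bound of 0.724 argues against an exchange with a gain of that size for the deposited cluster, although classes from marker lists gave 0.604. An exchange with a smaller gain cannot be told apart, because the interval of 0.724 to 1.06 allows it. The monocyte-like ratio of 0.864 (0.778 to 0.959) lies on the same side. A transgene transcript that is not counted under Nfil3 cannot be told apart from no overexpression, because the tables hold 0 features named after a transgene cassette. A biological reading, that the transgene was not active in these cells at this time, may hold as well and was not tested.

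A signal that stood out because it lies in barcodes the deposited cells leave out was that 626 wild type barcodes above the gene-number limit were given the monocyte-like class, against 73 in the library labelled transgenic (6.35% and 0.720% of barcodes). Doublets could give such barcodes: 15% (12.3 to 18.1) of the wild type ones were among the highest doublet scores, against 4.42% of deposited monocyte-like cells, and of simulated doublets of a monocyte-like cell with another class 52.1% (50.7 to 53.5) were. The simulated doublets were not limited to those above the gene-number limit or given the monocyte-like class. The 626 barcodes were also among their possible parents. So this comparison does not decide whether doublets of that kind were the main source. Doublets of monocyte-like cells with each other cannot be told apart from single cells, because 12.5% (9.55 to 16.0) of simulated ones reached the same score limit. Thinning the wild type library to the mean UMIs per barcode of the other, which does not match the whole spread of depth, left a wild type to transgenic ratio of 4.83 (3.76 to 6.28), from 8.52 before over all barcodes at or above the limit (629 and 76, a slightly wider set), which argues against the difference in mean depth as the whole source. A larger number of monocytes rich in transcripts in the wild type library stays open as a hypothesis.

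Ighg2c also stood out in barcodes left out of the deposited cells. It made up 2.01% of heavy-chain constant UMIs in immunoglobulin-rich barcodes of the library labelled transgenic, against 0.00946% in the wild type library. A pair of genes stood out because they went opposite ways in related classes, a difference that was not tested: the ratio of Mrc1 was 0.709 in macrophage-like and 1.72 in monocyte-like cells, and that of Tnf 0.690 and 1.72. After clustering again the monocyte-like ratio was 1.08 (0.863 to 1.35) for Mrc1, which leads the deposited macrophage-like cluster and no longer went the other way, and 1.71 for Tnf.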

How the results depend on the processing

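The alternatives that clustered the cells again, added barcodes above the gene-number limit or used finer deposited clusters were chosen after the results were seen. Of 2387 alternative values, 1822 stayed within the limits set around the reported value, 547 moved outside them, and 18 reversed. The limits were the counting interval for ratios, an interval from Poisson draws of the counts for list medians, and 1.5-fold for counts of genes. A ratio or median counted as reversed only where its reported interval left out no change and the alternative lay on the other side. Unless stated, the cause was not tested.

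The share of macrophage-like cells had a ratio of 1.30 with classes from marker lists and 2.18 after clustering again. That of monocyte-like cells was 0.345 with a class for each barcode, 0.312 after clustering again and 0.349 with high gene-number barcodes. Nfil3 in macrophage-like cells was at 0.604 with marker lists.

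Of the 24 genes named by rank in macrophage-like cells, 8 were named again with at least 200 UMIs, where fewer genes enter by construction, 15 without doublets, 14 with marker lists and 14 with high gene-number barcodes. Of the 10 in monocyte-like cells, 6 were named with marker lists and 5 in the finer cluster. With 2-fold as the size, fewer members pass by construction: 11 higher and 34 lower in macrophage-like cells (23 and 56 at 1.5-fold), 31 and 36 in monocyte-like cells (64 and 55).

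Cma1 in macrophage-like cells reversed to 1.03 without doublets, 2.22 after clustering again and 1.01 in the finer cluster. Mcpt4 reversed to 1.24, 4.44 and 2.73 there, to 1.41 with marker lists and to 1.95 with finer clusters weighted equally. In monocyte-like cells, clustering again reversed Retnla (0.301), Cd36 (0.552), Gpnmb (0.487) and Nfil3 (1.15), and the finer cluster Cxcl1 (2.38). Median-of-ratios scaling, which removes the shift of all genes by construction, turned Nfil3 (0.976) and the clock median (-0.0348) in neutrophil-like cells. It also moved the split of their list members from 68 higher and 53 lower to 36 and 71. Clustering again turned Il22 (0.366) and Cd163l1 (2.58) in T-like cells, and high gene-number barcodes Rgs5 (1.42) in fibroblast-like cells.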

Other observations

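No test of an explanation is reported in this part, and the cluster called ILC2-like was chosen after the data were seen.

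A finer deposited cluster led by Csf2, Il22, Calca, Gata3 and Il1rl1, called ILC2-like after group 2 innate lymphoid cells, held 257 and 497 cells (3.97% and 7.07% of the deposited cells). Type 2 genes were lower there in the library labelled transgenic for 6 of 11 members (median log2 ratio -0.70, percentile 0), with Il13 at 0.479 and Areg, an epidermal growth factor receptor ligand, at 0.511. Type 3 genes were lower for 7 and higher for 1 of 15 (median -0.56, percentile 0), with Il17a at 343 and 53 UMIs, a ratio of 0.0801 (0.0588 to 0.107), and the interleukin 1 receptor Il1r1 at 0.264. Cytotoxic genes were higher for 8 and lower for 1 of 12 (median 0.79, percentile 100), with Cd160 at 3.85. The T cell gene Cd8a was higher there as well, at 3.26 (1.84 to 6.2) and in 4.28% and 11.7% of cells, and markers of CD8 T cells summed to a ratio of 2.94 (2.60 to 3.32), so T cells within the cluster are not separated from innate cells. Type 1 genes were higher for 7 and lower for 2 of 14 (median 0.74), but without the 4 members that free RNA could give the median was 0.09. Medians were -0.09 for clock, 0.11 for dissociation and 0.10 for mitochondrial-encoded genes. Il22, a cytokine that acts on epithelium, had 14 and 379 UMIs there, with 99.2% of the latter in 5 cells.

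Plasma cells are seen in the immunoglobulin-rich barcodes, which were 12.4% and 11.4% of all barcodes. Igha, the heavy chain of IgA, made up 97.7% and 95.5% of their heavy-chain constant UMIs, Ighm 1.15% and 0.700%, Ighg2b 0.886% and 1.45%, Ighg1 0.0752% and 0.216%, and Ighg3 0.215% and 0.0976%. Of these barcodes 1155 and 1045 had at least 20 heavy-chain constant UMIs. Ighg2c led 0 of 1155 wild type barcodes, which allows a share of up to 0.319%, and 21 of 1045 barcodes of the library labelled transgenic. The secretory factor Mzb1 had a ratio of 0.706 (0.699 to 0.713), Xbp1 0.821 (0.809 to 0.833) and Jchain 1.01 (1.01 to 1.01), while Sdc1 was at 1.28 (1.22 to 1.34), Prdm1 at 1.12 (1.03 to 1.21), Derl3 at 1.02 and Tnfrsf17 at 1.03.

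Bex3 was higher in the library labelled transgenic in macrophage-like (3.31), dendritic-like (3.43) and B-like cells (5.16). It was higher as well in the larger finer monocyte-like cluster (9.55), in the finer cluster led by Arg1, Saa3 and Nos2 (7.23) and in an unnamed cluster of low UMI number (5.13). Xist had 0 UMIs in both libraries. Of Y-linked genes over the deposited cells, Ddx3y had a ratio of 1.33 (1.23 to 1.44), Eif2s3y 0.748 (0.684 to 0.819), Uty 1.03 (0.866 to 1.22) and Kdm5d 1.02 (0.864 to 1.20).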
